A study of Bos indicus with 24 samples.

How the data were processed

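Whole blood DNA from 24 cattle, labelled *Bos indicus* by the submitters, was profiled by whole-genome enzymatic methyl sequencing, which reads methylated cytosines after enzymatic rather than bisulfite conversion. The animals had developed from embryos cultured either with 1.8 mM choline chloride or with 1.8 mM sodium chloride as the control. There were 4 groups of 6 animals, female and male, choline and control, and per the labels the sampled animals were picked at random within each group. Each library came from a different animal.

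The submitters' processing notes name fastp 0.23.1, Bismark, DRAGEN, methylKit 1.20.0, ChIPseeker 1.32.1 and the bovine genome build ARS-UCD1.2, without giving the role or order of each. The deposited tables, 1 per sex, hold percent methylation of CpG sites per library in tiles of 500 bases that start every 250 bases, as made by the authors. A tile was listed where at least 5 libraries of each group had a value. The authors also deposited a p-value, a q-value and a difference in percentage points for choline against control in each tile, from a comparison with covariates that are not named. The sign of that difference equalled choline minus control of the library means in 99.95% of female and 99.95% of male tiles with a difference of at least 5 points. The assigned gene, the annotation class and the distance to the transcription start site (TSS) were taken from the same tables. The assigned gene is the one given for the tile, which need not contain it, and an intron or exon class can belong to another gene. The tables also hold 72 numbered columns of coverage and of methylated and unmethylated counts that name no sample, and these were not used here. The read depth behind each library's value is therefore unknown here, no count-based model was fitted, and no counting interval is given. A model of counts had been foreseen in case counts could be tied to libraries. Percentages from few reads carry more error than those from many, and the tests treated them alike.

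Neighbouring tiles share bases, so tests used the non-overlapping tiles, 3009805 in females and 2884899 in males. Differences in percent methylation were tested with limma's moderated test, two-sided, with the Benjamini-Hochberg adjusted p threshold at 0.05. It was written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and was checked against limma 3.58.1 in R 4.3.3 on simulated data. Figures were drawn with matplotlib 3.10.9. Within each sex, 6 choline libraries were compared with 6 control libraries without covariates. The mean of the female and male differences, and the difference between them, were tested over all 24 libraries on the 2772180 tiles in both tables, with the 4 group means fitted and a common variance. Promoter methylation was the mean of a gene's non-overlapping tiles within 1000 bases of the TSS that had a value in every library, with at least 2 tiles. Mean methylation over tiles, over 14 annotation, chromosome and level classes and over the promoters of 12 gene lists was compared with exact two-sided permutation tests over every assignment of the 12 libraries of a sex to the groups, for which 0.00216 is the smallest possible p. The p-values of classes and of lists were adjusted within a sex. On simulated data with the same spread and 50 changed features per size, the tile test called 0.0% of planted differences of 10 points in either sex. It called 16.0% of planted differences of 20 points and 58.0% of those of 40 points in females, and 16.0% and 62.0% in males. The promoter test called 64.0% of planted differences of 10 points in females and 86.0% in males. Changes were planted only in features of intermediate mean. Simulated values were cut to the possible range, so some large planted differences ended up smaller than named. Among unchanged features, 5 tiles were called in females and 0 in males, and 12 promoters in females and 10 in males.

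The authors' calls here are tiles with a deposited q-value under 0.05 and a difference of at least 20 points, thresholds applied here. Such tiles were merged into regions where they overlapped or adjoined. Regions and genes were named by rules written before the data were examined. They took up to 10 tiles or regions per direction and sex with the largest difference. For the authors' regions this was restricted to regions of at least 2 tiles with a gene symbol whose 6 choline and 6 control values did not overlap in the tile with the smallest q-value. They also took the 3 promoters per direction with the smallest p where none passed, up to 2 members of each list with the smallest promoter p, and up to 5 tiles per direction over both sexes. Tiles called by limma are all named, including those without a gene symbol, which departs from the rule that only genes with a symbol be named. Calls shared between the sexes were tested with Fisher's exact test, two-sided, per direction. A comparison of the sexes on autosomes, added after the tests had been fixed, used the same moderated test on 2746379 tiles.

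Alternatives were a log2 ratio scale with a pseudocount of 1, tiles with a mean of 10 to 90%, the tiles offset by 250 bases, all overlapping tiles, tiles with a value in every library, libraries shifted to a common mean, a promoter window of 3000 bases, a minimum of 1 tile per promoter, stricter and looser thresholds on the authors' calls, pairing libraries by replicate number, and leaving out each library. Each result was also compared with other splits of the same libraries. The labels name no batch. The gene lists, tests and alternatives were fixed before the data were examined, apart from the comparison of the sexes, the summaries of the mitochondrial genome and of X promoters, and those named in the closing parts as chosen afterwards.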

Results

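Percent CpG methylation was measured in whole blood of 24 cattle derived from embryos cultured with choline chloride, a methyl-donor precursor, or with sodium chloride as the control, in 4 groups of 6 animals. The female table held 6018232 overlapping tiles, and 5769552 were listed for males. The share of non-overlapping tiles without a value was 1.74% ± 1.26 in female controls and 1.64% ± 1.38 in female choline libraries, and 1.62% ± 1.70 and 1.86% ± 1.72 in the male groups (SD, n = 6 each). Read depth per library is unknown here. Positions refer to ARS-UCD1.2.

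In females, the comparison asked whether blood methylation differed between animals from choline-cultured and control embryos. Methylation rose at a tile assigned to *MUC13*, which encodes a transmembrane mucin, from 72.3% ± 3.29 to 92.1% ± 1.81 (SD, n = 6 and 6; chromosome 1, 69347001 to 69347500, in the class of promoters beyond the nearest windows, 2323 bases from the TSS). It rose near *CCNI*, a cyclin gene, from 71.2% ± 3.13 to 90.6% ± 1.44 (chromosome 6, 91929501 to 91930000, intergenic). It fell near *RGS4*, a regulator of G-protein signalling, from 55.3% ± 6.66 to 17.6% ± 4.94 (chromosome 3, 6304501 to 6305000, intergenic). It also fell at an intronic tile of *PPP2R2C*, a regulatory subunit gene of protein phosphatase 2A, from 79.6% ± 2.11 to 56.1% ± 2.20 (chromosome 6, 102766001 to 102766500). An intergenic tile assigned to ENSBTAG00000048936, a gene without a symbol, rose from 21.1% ± 7.18 to 77.1% ± 7.66 (n = 6 and 5; chromosome 6, 106006001 to 106006500). These 5 tiles, 3 higher and 2 lower, were all that passed among 3009805 tested by limma, with an adjusted p of 0.00521 for *PPP2R2C* and 0.0325 for the other 4. The choline and control values did not overlap in any of the 5. An unadjusted p under 0.05 was found for 160114 tiles, 5.32% of those tested. The count ranged from 1 to 31 when single libraries were left out, and 13 of 100 splits of the female libraries gave at least 5 tiles. On the log2 scale 0 of these 5 tiles passed by limma.

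No female promoter passed the limma test among 23912, with 1258 at an unadjusted p under 0.05 and a smallest adjusted p of 0.419. The smallest p belonged to a promoter without a gene symbol. Among genes with a symbol, the promoters with the smallest p and higher values with choline were *MIR2285BQ*, at 75.4% ± 1.34 and 84.1% ± 3.44 in control and choline libraries, *DHTKD1*, a mitochondrial dehydrogenase gene, at 34.9% ± 1.61 and 40.2% ± 1.69. *MIR1193* stood at 88.3% ± 1.67 and 92.7% ± 1.18. Those with lower values were *ANKRD37*, at 47.3% ± 2.73 and 41.5% ± 1.80, *DBH*, the gene of the enzyme that makes noradrenaline from dopamine, at 84.2% ± 2.05 and 79.8% ± 1.38. *SNX27*, a sorting nexin gene, was at 43.2% ± 3.82 and 35.8% ± 2.25 (SD, n = 6 each).

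Among the lists fixed in advance, 0 members passed in females by limma over all genes and 0 when adjusted over the list alone. Of 47 measured promoters of choline and one-carbon metabolism genes, 1 had an unadjusted p under 0.05, *PCYT1A*, of the phosphatidylcholine pathway, at 25% ± 1.61 and 22% ± 2.09. The folate receptor gene *FOLR1* stood at 87.5% ± 2.26 and 89.5% ± 0.879. Of 30 promoters of DNA and histone methylation genes, *TET1*, of a 5-methylcytosine dioxygenase, was at 87.3% ± 0.663 and 89.9% ± 1.82. *DNMT1*, of the maintenance methyltransferase, was at 53.1% ± 0.928 and 54.2% ± 0.718. Both differences turned negative with a window of 3000 bases. Of 36 imprinted promoters 0 had an unadjusted p under 0.05, with *PEG10* at 43.8% ± 7.23 and 49.9% ± 3.43 and *IGF2R* at 27% ± 1.47 and 25.3% ± 1.37. The difference at *PEG10* turned negative with a window of 3000 bases. Among 47 growth genes, *FGFR3*, a receptor in bone growth, was at 12.1% ± 1.27 and 13.9% ± 1.39 and *ADCY9* at 28.3% ± 0.789 and 27.1% ± 0.737. Among 40 insulin and lipid genes, *ACACA* was at 71.4% ± 0.990 and 70.2% ± 0.368 and *ADIPOQ* at 84.7% ± 3.51 and 81.2% ± 3.36. Of 54 developmental transcription factor promoters 39 were higher with choline and 2 had an unadjusted p under 0.05, *HOXB3* at 82.6% ± 0.947 and 86.4% ± 1.99 and *HOXD4* at 37.7% ± 6.83 and 31.2% ± 1.90. Promoters of the same animals are not independent, so the count of higher ones is not a test. Among 34 germline genes, *TDRD5* was at 63.6% ± 2.38 and 69.7% ± 4.41 and *DDX4* at 83.9% ± 2.66 and 86.5% ± 1.37 (control and choline, SD, n = 6 each).

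The blood cell marker lists in females also held no promoter that passed by limma. Of 21 neutrophil and eosinophil promoters 20 were higher with choline, with *PADI4* at 43.9% ± 2.0 and 48.3% ± 3.18 and *MMP8* at 77.4% ± 2.25 and 80.6% ± 3.81. Of 21 monocyte promoters 16 were higher, with *MARCO* at 54.9% ± 7.25 and 66.1% ± 7.93 and *CD86* at 49.6% ± 2.84 and 52.2% ± 1.04. Of 21 B cell promoters 5 were higher, with *VPREB3* at 73.1% ± 6.28 and 67.1% ± 4.46. Of 34 T and NK cell promoters 17 were higher, with *IL7R* at 46.4% ± 3.26 and 40.3% ± 2.48 and *GZMM* at 69.8% ± 3.60 and 67.1% ± 1.48. Of 20 red cell and platelet promoters 13 were higher, with *TFRC* at 8.58% ± 0.790 and 7.42% ± 1.02 and *GP9* at 53.9% ± 3.99 and 56.3% ± 1.67 (control and choline, SD, n = 6 each). The difference at *GZMM* reversed on the offset tiles and that at *TFRC* with a window of 3000 bases. The list means differed by less than their spread allowed to call, with adjusted exact permutation p values of 0.649 or more.

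The authors' comparison in females gave 13076 tiles with a q-value under 0.05 and at least 20 points, in 10729 regions, of which 5943 were higher and 4786 lower with choline. Intergenic tiles made up 66.1% of the called non-overlapping tiles and 53.8% of those tested, exons 1.24% and 4.31%, and promoters within the nearest window 1.59% and 4.11%. Regions with higher values whose groups did not overlap included *CPNE5*, a copine gene, with 62.5% ± 15.9 and 96.5% ± 1.61 in its promoter (chromosome 23, 10740501 to 10741000), *PFKFB3*, a regulator of glycolysis, with 43.9% ± 11.1 and 83.2% ± 15.1 in an intron (chromosome 13, 17266251 to 17266750). In intergenic tiles, these regions also included *CENPC* with 34.1% ± 2.37 and 74.9% ± 18.5, *CGN1* with 50.7% ± 14.1 and 85.2% ± 9.45 and *PCDH17* with 17% ± 3.38 and 49.1% ± 17.6. Those with lower values included *KCNMA1*, a potassium channel gene, with 73.6% ± 13.3 and 40.2% ± 12.8 in an intronic tile -32280 bases from its TSS (chromosome 28, 33193251 to 33193750), and *SNX27* with 85.2% ± 16.5 and 49.7% ± 10.6 in an intron. They also included the intergenic tiles assigned to *ZFAT* with 80.6% ± 14 and 28.2% ± 15.8, *MB21D2* with 43.1% ± 19.6 and 1.90% ± 4.65, *ATP10A* with 78.4% ± 7.66 and 44.7% ± 15.9 and *NREP* with 77.6% ± 14.5 and 53.0% ± 7.23 (control and choline, SD, n = 6 each). Of these intergenic tiles in either direction, that of *NREP* lay nearest to the TSS, at -3312 bases, and that of *PCDH17* farthest, at -1228218 bases. Uncharacterised loci and microRNA genes named by the same rule were *LOC112443349* (12.5% and 62.1%), *LOC112447233* (31.5% and 73.4%), *MIR2420* (11.3% and 54.9%), *LOC107131254* (41.7% and 84%) and *MIR2284Q* (27.8% and 59.8%). With lower values they were *LOC112447214* (86.3% and 39.7%), *LOC112444801* (48.4% and 7.58%), *MIR2489* (71.9% and 35.2%) and *LOC112443062* (79.8% and 46%). Of 6539 called non-overlapping tiles, the groups did not overlap in 538, or 8.23%, against 0.269% of all tiles. Of the 6539, limma gave an unadjusted p under 0.05 for 70.4% and an adjusted p under 0.05 for 3. Tiles picked by a large difference in these same libraries favour such separation and low p-values, so these shares do not test the calls.

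In males, the same comparison gave a rise at an exonic tile of *ECI2*, an enzyme gene of fatty acid oxidation, from 49.5% ± 7.13 to 90.8% ± 5.95 (SD, n = 6 each; chromosome 23, 50049001 to 50049500). Methylation rose at an intergenic tile assigned to *FN1*, the fibronectin gene, from 33.1% ± 3.12 to 60.8% ± 4.71 (chromosome 2, 103571001 to 103571500, -139529 bases from the TSS). It fell at intronic tiles assigned to *RPN2*, of the oligosaccharyltransferase complex, from 66.0% ± 4.53 to 35.6% ± 3.64 (n = 6 and 5; chromosome 13, 66119501 to 66120000) and *CYP3A24*, a cytochrome P450 gene, from 92.4% ± 4.67 to 66.1% ± 3.31 (chromosome 25, 36736001 to 36736500). An intergenic tile of ENSBTAG00000049872 fell from 94.2% ± 1.65 to 71.2% ± 3.27 (chromosome 9, 91275501 to 91276000). These 5 of 2884899 tiles passed by limma, 2 higher and 3 lower, with an adjusted p of 0.0212 for the last and 0.0456 for the other 4, and their groups did not overlap. An unadjusted p under 0.05 was found for 176489 tiles, 6.12%. Leaving out single libraries gave 0 to 31 tiles, and 15 of 100 splits of the male libraries gave at least 5. On the log2 scale 1 of these 5 tiles passed by limma, that of ENSBTAG00000049872.

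No male promoter passed by limma among 23054, with 1345 at an unadjusted p under 0.05 and a smallest adjusted p of 0.454. Among genes with a symbol, the smallest p among higher values belonged to *RBSN*, of endosomal trafficking, at 50% ± 0.781 and 53.2% ± 0.780, with *LOC112448358* at 84.5% ± 2.5 and 91.2% ± 2.03 and *LOC112449393* at 62.8% ± 2.51 and 69.8% ± 2.38. Among lower values they belonged to *SVIL*, the supervillin gene, at 82.3% ± 2.27 and 75.6% ± 0.958, *GPX1*, glutathione peroxidase, at 25.5% ± 1.01 and 22.4% ± 0.232, and *LOC112444659* at 79.3% ± 2.54 and 67.9% ± 4.98 (control and choline, SD, n = 6 each).

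In the male lists 0 members passed by limma, over all genes or adjusted over the list alone. Of 46 one-carbon promoters 4 had an unadjusted p under 0.05, among them *AHCY*, which clears S-adenosylhomocysteine, at 63.6% ± 0.651 and 61.8% ± 0.946 and *SHMT1*, a folate-cycle enzyme, at 64% ± 0.427 and 65.4% ± 0.747. Of 29 methylation machinery promoters 3 did, with *MBD4* at 50.3% ± 2.80 and 46.9% ± 1.64 and *DNMT3L*, a cofactor of germline methylation, at 79.2% ± 2.72 and 75.2% ± 2.83. Of 47 growth genes 2 did, *PRKAG3* at 75.4% ± 2.21 and 80.2% ± 2.07 and *LIN28B* at 2.79% ± 0.494 and 5.05% ± 1.81. The difference at *PRKAG3* reversed on the offset tiles. Of 35 imprinted promoters 0 did, with *PPP1R9A* at 2.40% ± 0.584 and 3.54% ± 0.915 and *PON1* at 42.1% ± 5.27 and 48.8% ± 7.47. That at *PPP1R9A* reversed with a window of 3000 bases. Of 54 developmental transcription factor promoters 45 were higher with choline and 1 had an unadjusted p under 0.05, the pluripotency gene *NANOG* at 81.5% ± 2.63 and 75.1% ± 4.76. The count of higher promoters is again not a test. In a comparison over both sexes, chosen afterwards, the mean of this list did not pass (exact permutation p = 0.213, adjusted p = 0.491). *NKX2-5* was at 14.2% ± 1.99 and 16.6% ± 2.06. The insulin receptor gene *INSR* was at 85.3% ± 1.45 and 84.0% ± 0.775, *SREBF1* at 38.6% ± 1.53 and 40% ± 0.973. The germline genes *TEX14* and *SYCP3* were at 63.9% ± 2.86 and 60% ± 2.14 and at 87.7% ± 3.28 and 91.0% ± 1.19 (control and choline, SD, n = 6 each).

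Of the marker lists in males, the red cell and platelet promoters had the smallest p, with a mean of 50.3% ± 0.362 in control and 51.1% ± 0.660 in choline libraries (SD, n = 6 each; exact permutation p = 0.0130, adjusted p = 0.156). It held *ANK1*, the erythrocyte ankyrin gene, at 86.7% ± 1.43 and 89.3% ± 1.81. Of 21 neutrophil promoters 13 were higher with choline, with *S100A8* at 60.4% ± 6.00 and 66.0% ± 4.99 and *LTF* at 42.1% ± 3.45 and 45.3% ± 2.78. Of 19 monocyte promoters 16 were higher, with *CSF1R* at 77.3% ± 2.40 and 80.7% ± 1.55 and *CCR2* at 70% ± 6.14 and 75.1% ± 3.58. Of 21 B cell promoters 4 were higher, with *EBF1* at 3.17% ± 0.986 and 2.05% ± 0.565. Of 34 T and NK cell promoters 18 were higher, with *PRF1* at 75.5% ± 2.10 and 71.9% ± 2.88 and *CD6* at 57.1% ± 2.29 and 54.1% ± 3.13 (control and choline, SD, n = 6 each).

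The authors' comparison in males gave 12997 called tiles in 10648 regions, 5394 higher and 5254 lower with choline. *ECI2* was also among these regions, with 39.7% ± 5.96 and 88.1% ± 10.6 in an exonic tile (chromosome 23, 50049251 to 50049750) of a region of 4 tiles. Further regions with higher values were *KNG1*, of kininogen, with 47.2% ± 15.3 and 88.5% ± 11.5 in an intron. Intergenic tiles with higher values were assigned to *SEC23IP* with 12.8% ± 10.9 and 75.4% ± 26.9, *STAB2* with 11% ± 12.7 and 69.6% ± 24.6, *CLDN23* with 25.8% ± 8.97 and 79% ± 19.7, *LY86* with 47% ± 10.4 and 90.4% ± 5.10, *F13A1*, the gene of coagulation factor XIII A chain, with 54.5% ± 12.7 and 91.0% ± 4.5 and *TNKS* with 46.7% ± 11.3 and 86.3% ± 10.2. Lower values were found at *HS6ST3*, a heparan sulfate sulfotransferase gene, with 81.9% ± 15 and 36.4% ± 10.4 in an intron. They were also found in intergenic tiles assigned to *SMC2* with 60.2% ± 14.9 and 18% ± 10.3, *BRMS1L* with 77.6% ± 15.3 and 32.7% ± 21.4, *ERCC4*, a DNA repair gene, with 68.5% ± 7.67 and 40.8% ± 9.46 and *GMDS* with 82.4% ± 9.40 and 52.0% ± 9.87 (control and choline, SD, n = 6 each). Of these intergenic tiles in either direction, that of *F13A1* lay nearest to the TSS, at -58841 bases, and that of *ERCC4* farthest, at -452685 bases. *RAD23B* was assigned to regions of both directions, 1 with 47.5% ± 13.5 and 91.8% ± 2.39 and 1 with 80.9% ± 13.5 and 46.0% ± 8.26. The rule also named *LOC112448303*, with regions of both directions (31.4% and 76.8%, and 65.2% and 33.7%), *LOC112444946* (75% and 39.1%), *LOC112447214* (77.5% and 39.9%) and *MIR2286* (86.2% and 54.8%). Of 6459 called non-overlapping tiles, the groups did not overlap in 622, or 9.63%, against 0.335% of all tiles. Of the 6459, limma gave an unadjusted p under 0.05 for 76.4% and an adjusted p under 0.05 for 5. As in females, picking tiles by their difference in these same libraries favours both shares, which therefore do not test the calls.

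Over both sexes, the question was which tiles differed with choline in the mean of the female and male differences. *COL26A1*, a collagen gene, fell at 2 intronic tiles. The first fell from 77.9% ± 4.14 to 59.8% ± 6.99 in females and from 77.7% ± 4.51 to 61.4% ± 4.92 in males (chromosome 25, 35380001 to 35380500). The other fell from 81.5% ± 4.08 to 65.2% ± 4.06 and from 82.2% ± 2.06 to 70.1% ± 6.37 (chromosome 25, 35330501 to 35331000). An intronic tile of *MACROD2*, of ADP-ribose hydrolysis, fell from 79.8% ± 4.88 to 61.9% ± 2.92 and from 75.6% ± 4.87 to 66.6% ± 4.49 (chromosome 13, 9732001 to 9732500). An intergenic tile assigned to *SLITRK5*, a neuronal membrane protein gene, lay -109920 bases from its TSS. It rose from 50.7% ± 4.18 to 62.6% ± 5.33 and from 44.5% ± 4.39 to 65.3% ± 5.46 (chromosome 12, 62185501 to 62186000, n = 5 in the male choline group). The intergenic tile assigned to *GLT1D1*, a glycosyltransferase gene, lay 130764 bases from its TSS. It rose from 48% ± 6.82 to 63.2% ± 2.22 and from 41.9% ± 4.32 to 58% ± 5.01 (chromosome 17, 48103501 to 48104000).

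Tiles of 3 genes without a symbol also passed over both sexes. ENSBTAG00000051788 rose from 54.9% ± 4.04 to 68.3% ± 6.95 in females and from 44.3% ± 5.46 to 67.2% ± 6.14 in males (chromosome 21, 66632501 to 66633000, intergenic). ENSBTAG00000051182 fell from 71.2% ± 4.39 to 55.9% ± 7.26 and from 85.2% ± 3.49 to 63.1% ± 5.04 (chromosome 28, 15092501 to 15093000, intergenic; n = 5 in the male choline group). ENSBTAG00000055083 fell from 87.5% ± 2.31 to 77.1% ± 4.77 and from 90.4% ± 2.59 to 76.2% ± 5.30 (chromosome 28, 40406501 to 40407000, intronic; SD, n = 6 unless given). These 8 of 2772180 tiles passed by limma, 3 higher and 5 lower, with an adjusted p of 0.0430 for *MACROD2* and ENSBTAG00000055083 and 0.0283 for the other 6. An unadjusted p under 0.05 was found for 187584 tiles, 6.77%. On the tiles offset by 250 bases 0 passed, although the offset tile at *COL26A1* next to the first differed by -24.4 points, with a limma adjusted p of 0.138, and that at *GLT1D1* by 12.9 points, with a limma adjusted p of 0.191. Offset tiles also differed in the direction of the called tile at ENSBTAG00000051788, by 23.2 points on one side, at the other *COL26A1* tile, by -17.1, at *MACROD2*, by -16.5 and -8.38, and at ENSBTAG00000051182, by -10.1. Smaller differences were found elsewhere, with 1.72 points at the offset tile of *SLITRK5*, -4.45 and -2.24 at those of ENSBTAG00000055083 and -0.787 on the other side of ENSBTAG00000051788. At the first *COL26A1* tile the other offset tile differed by -0.914. At the next non-overlapping tiles the difference was -11.2 at the other *COL26A1* tile and -11.2 at ENSBTAG00000051182, in the direction of the called tiles, and 11.3 at *MACROD2*, 8.59 at ENSBTAG00000055083 and -4.30 at *GLT1D1*, opposite to it. The remaining next tiles differed less, by -0.407 and 3.32 at ENSBTAG00000051788, 2.42 at *SLITRK5*, 0.504 at the first *COL26A1* tile and -3.19 on the other side of ENSBTAG00000055083. On the log2 scale 1 of the 8 tiles passed by limma, that of ENSBTAG00000051182. Leaving out single libraries gave 0 to 31 tiles.

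**Figure D1:**
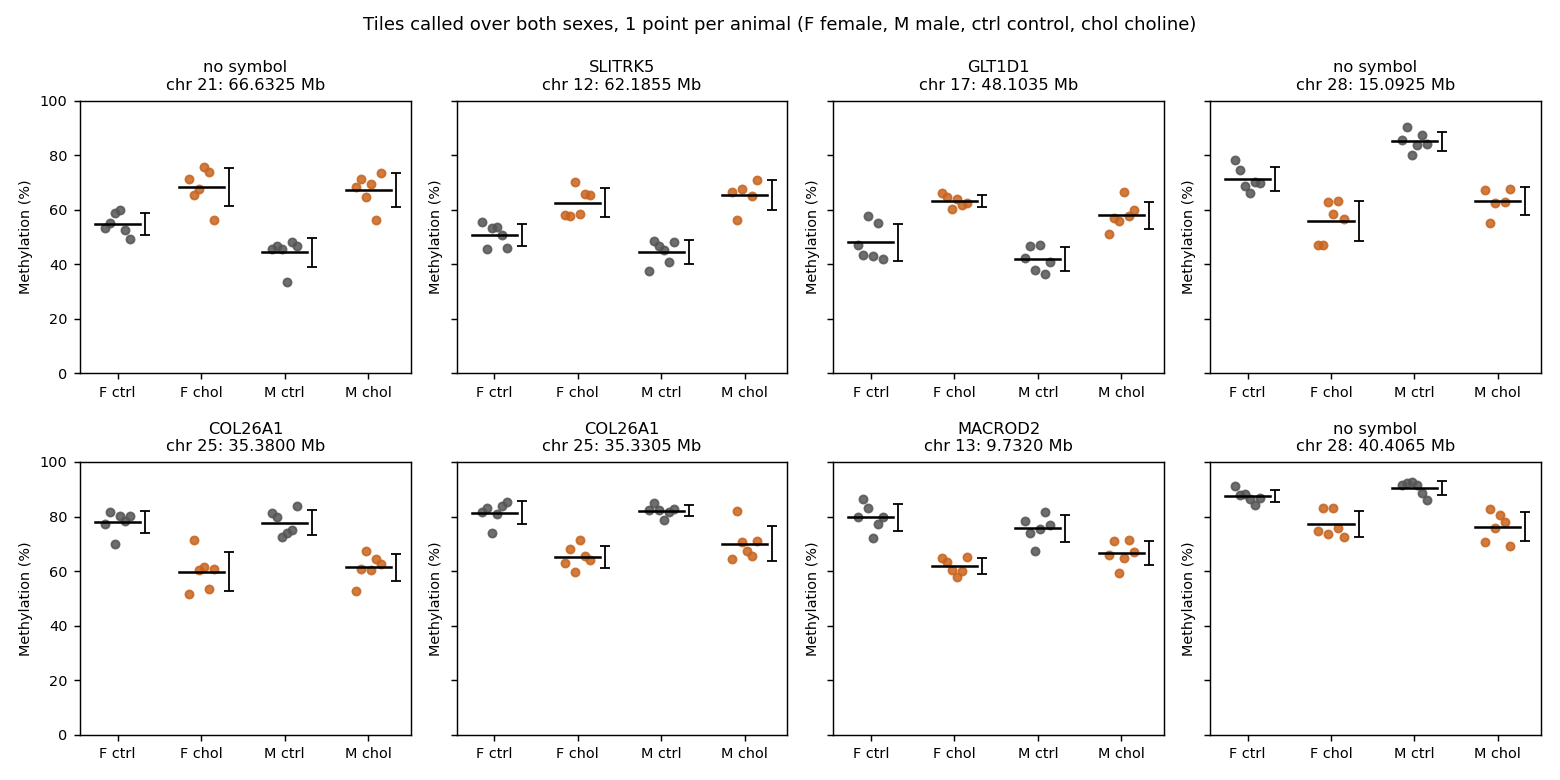
Percent methylation (y axis) of each animal at the 8 tiles that passed over both sexes, in 4 groups of 6 animals (x axis), where lines are group means, bars are 1 SD and points are missing where a library had no value. At *GLT1D1* the female control mean is 48% and the female choline mean 63.2%.

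No promoter passed over both sexes by limma among 22395, with 1517 at an unadjusted p under 0.05 and a smallest adjusted p of 0.129. The test of the difference between the male and female effects called 0 of 2772180 tiles, with 126634 at an unadjusted p under 0.05, and 0 of 22395 promoters, with 925 at an unadjusted p under 0.05. No effect of choline at a tile or promoter was therefore shown to differ between the sexes.

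Mean methylation over all tiles was 78.8% ± 0.616 in female control and 79% ± 0.691 in female choline libraries, a difference of 0.249 points (SD, n = 6 each; exact permutation p = 0.528). In males it was 79.2% ± 0.532 and 78.9% ± 0.683, a difference of -0.245 (exact permutation p = 0.502). Over the 2152827 tiles with a value in all 24 libraries, a different set of tiles, the effects were 0.229 and -0.239 points and the male minus female difference was -0.468 (exact permutation p = 0.351). Promoters within the nearest window had the lowest mean of the annotation classes, 51.8% ± 0.386 in female controls, and exons the highest, 86.2% ± 0.384. No annotation, chromosome or level class passed, with adjusted exact permutation p values from 0.649 in females and from 0.727 in males. In the mitochondrial genome, 33 tiles averaged 0.404% ± 0.0334 in female control and 0.340% ± 0.00908 in female choline libraries (exact permutation p = 0.00216, the smallest possible), and 0.268% ± 0.0292 and 0.268% ± 0.0168 in males (exact permutation p = 0.957). This mitochondrial summary was not fixed in advance. Its levels lie near 0, and no background level of the enzymatic conversion was used here to compare them with.

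**Figure D2:**
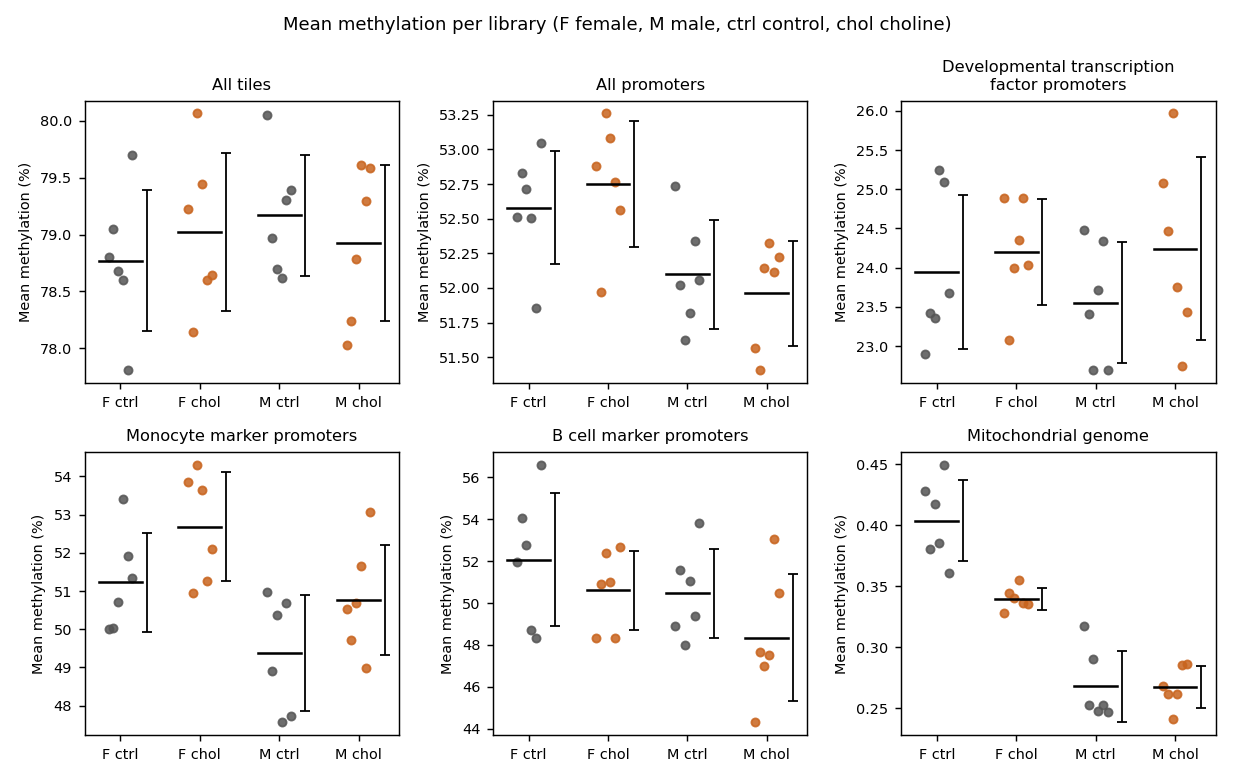
Mean percent methylation per library (y axes, not starting at 0) over all tiles, all promoters, promoters of 3 gene lists and the mitochondrial genome, in 4 groups of 6 animals (x axis), where lines are group means and bars are 1 SD. Means over all tiles lie between 78.8% and 79.2% in the 4 groups, and the mitochondrial means are 0.404% in female controls and 0.268% in male controls.

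The authors' calls were compared between the sexes on 2772180 shared tiles. Called tiles of both sexes numbered 433, of which 331 had the same direction, 168 higher and 163 lower with choline, and 102 opposite directions. The same-direction count was 58.1 times and the opposite-direction count 18 times that of independent calls. The same-direction multiple was 20.8 when calls within 1000 bases counted as shared and 141 at the stricter thresholds. Fisher's exact tests, two-sided, gave p = 2.94e-223 for higher in both and p = 2.75e-233 for lower in both, and p = 1.92e-51 and p = 1.87e-39 for the opposite directions, but they count tiles as independent. Such an excess also arose without the treatment groups. For tiles with a difference of at least 20 points in both sexes and values in all 24 libraries, the same-direction and opposite-direction counts together were 52.7 times those expected in the real pair of groups, against a median of 71.6 in other pairs of splits (highest 175), and 193738 of 213444 pairs were as high as the real one. The groups did not overlap in both sexes in 0 of the 331. Of these, chosen after their values were seen, an intronic tile of *RICTOR*, of the mTORC2 complex, stood at 61.1% ± 25.1 and 95.7% ± 4.46 in females and 62.3% ± 27.3 and 93.1% ± 3.87 in males (control and choline, SD; chromosome 20, 35311001 to 35311500). An intergenic tile assigned to the distant gene *ERCC4* was at 78.6% ± 6.24 and 41.1% ± 26.5 and at 76.6% ± 9.56 and 38.7% ± 6.58 (chromosome 25, 12380501 to 12381000). Across 2152827 tiles, which are not independent replicates, female and male differences had a Pearson r of 0.132 (exact permutation p = 0.186 over pairs of splits).

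The comparison of the sexes whatever the treatment was not among the tests fixed in advance. In it, 299 of 2746379 autosomal tiles passed by limma, 282 lower and 17 higher in males. The largest group lay on chromosome 17 at *ZNF280B* and *ZNF280A*, which encode zinc finger proteins, with 14 and 16 tiles. Male values there may include reads of Y chromosome copies, which were not told apart from the autosomal genes. A tile in the 3' UTR of *ZNF280B* (70981001 to 70981500) was at 93.4% ± 4.99 in females and 7.58% ± 0.696 in males. A tile in the promoter of *ZNF280A* (71003501 to 71004000) was at 83.1% ± 7.49 and 15.7% ± 2.61 (SD, n = 12 each). Lower levels in males were also found at 11 tiles of *GABBR2*, a GABA receptor gene, with medians of 90.7% and 75.1%, and in the promoter of *AMBP* (chromosome 8, 103331501 to 103332000) at 94.0% ± 4.75 and 64.5% ± 5.36. Higher levels in males were found at 3 tiles of *FAP*, among them 51.2% ± 10.4 and 80.6% ± 13.4 (chromosome 2, 34180001 to 34180500). On the X chromosome, 589 promoter tiles averaged 54.4% ± 0.824 in females and 41.2% ± 0.435 in males, against 50.5% ± 0.392 and 50.4% ± 0.356 over autosomal promoter tiles. These tiles had a value in all 24 libraries and need not stand for all X promoters. Males had 20569 non-overlapping X tiles listed, against 119988 in females. The genes of this comparison were picked by their number of tiles and size of difference.

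**Figure D3:**
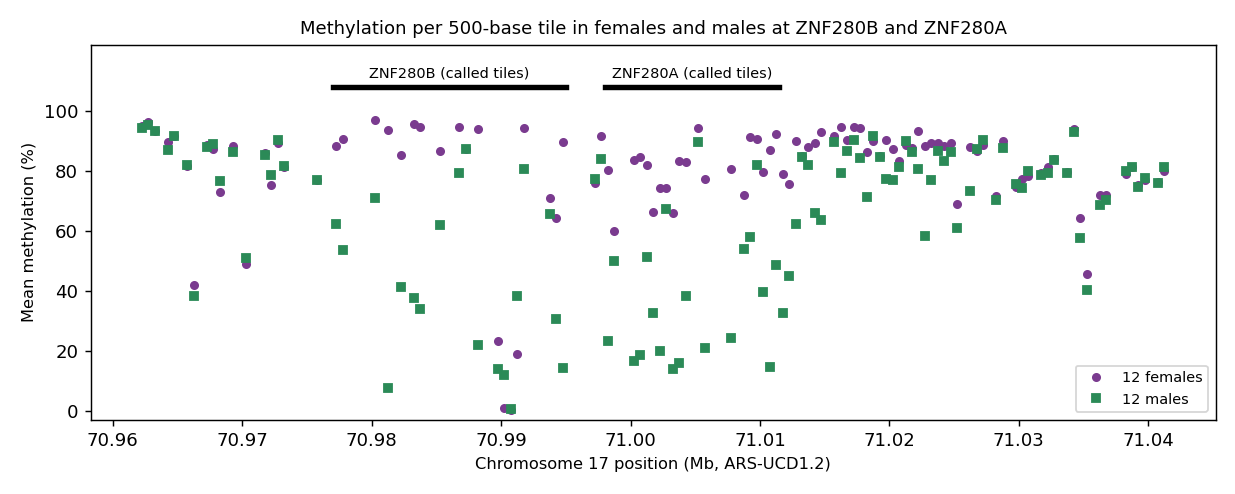
Mean methylation (y axis, percent) of 12 females and 12 males per non-overlapping tile along chromosome 17 (x axis, Mb), where bars span the called tiles assigned to *ZNF280B* and *ZNF280A*. Within the block from 70977001 to 71026500 the median of called tiles is 87.0% in females and 43.1% in males. Male values may include reads of Y chromosome copies.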

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

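The test of reads from Y chromosome copies was chosen only after the result was seen, as was the reading of the ratio for tiles shared between the sexes, and the lists and signs of the marker score were picked after their differences with choline were seen.

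A library far from the other 5 of its group was found in 17 of 380 groups, 4.47%, where chance gives about 1 in 20. For lists and classes, these were a female choline library at 39.4% on imprinted promoters (median of the others 42.0%), a female choline library at 36.3% on growth promoters (37.7%) and a male control library at 83.7% in 5' UTRs (83.0%). Among tiles of the authors' regions in females, they were control libraries at 0.0% at *LOC112443349* (14.5%), at 0.0% at *LOC112447233* (39.6%) and at 7.02% at *MIR2284Q* (32.1%), and choline libraries at 67.1% at *CGN1* (87.9%), at 11.4% at *MB21D2* (0.0%) and at 29.4% at *SNX27* (52.5%). In males, they were control libraries at 35.4% at *STAB2* (3.70%) and 79.5% at *F13A1* (49.7%), and choline libraries at 87.2% at *RAD23B* (92.3%) and 22.3% at *ERCC4* (43.1%). A male control library stood at 33.3% at the chromosome 21 tile of ENSBTAG00000051788 (46.6%). For promoters, female choline libraries stood at 82.5% at *DBH* (79.2%) and 69.9% at *GZMM* (66.3%), and a female control library at 40.7% at *MARCO* (58.8%).

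At the thresholds applied here, the authors' comparison gave 10729 regions in females and 10648 in males, while limma called 5 tiles in each sex. Chance splits of the animals cannot be excluded, since 26 of 100 splits of the female libraries gave as many non-overlapping tiles with a difference of at least 20 points as the real 5952 (highest other split 14578), and 9 of 100 did in males for the real 6331 (highest other 10364), which points to structure among the animals. Differences between animals whatever their group, such as sequence variants, are a candidate explanation. Of the called tiles, 64.7% in females and 62.5% in males had a within-group SD above the 90th percentile of tiles of the same mean level, against 10% of all tiles. Picking tiles by a difference of at least 20 points favours a wide spread, and few reads widen it too. The share therefore does not single out this explanation. Fewer reads behind the called tiles may also contribute, since called tiles lacked a library 1.93 times as often as tiles of the same level in females and 2.0 times in males. An effect of choline on part of the regions stays open.

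Tiles called from the authors' comparison in both sexes had the same direction more often than opposite directions, by a ratio of 3.23 of observed over expected counts. The bound set in advance for excluding calls that fall in either direction was met by the interval of that ratio, 2.58 to 4.03, but the bound was wrong because the interval counts tiles as independent. Splits show that they are not: over tiles with a difference of at least 20 points in both sexes and values in all 24 libraries, 162 in the real groups, 58109 of 213444 pairs of a female and a male split, 0.272 of them, gave a same-direction share as far from 50 percent as the real 79% (highest other 100%; 76.4% for the authors' calls), so chance cannot be excluded and calls in either direction cannot be told apart from a shared effect. A different mix of blood cells could not be told apart either, since 48% of the same-direction tiles followed a score of marker promoters within groups (one-sided permutation p = 0.560) and the middle 95% of permuted scores gave 30.2% to 70.7%. The score itself was higher with choline by 3.06 points in females and 3.29 in males, but its lists and signs were picked from such differences. A shared effect of choline in the embryo stays open.

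The sexes differed at 299 autosomal tiles, and chance can be excluded, since 1 of 100 splits within treatment, the real one, gave as many (highest other 32). Reads of Y chromosome copies placed on autosomes may underlie the block at *ZNF280A* and *ZNF280B*, where 40 of 44 tiles, 90.9%, had ranges that did not overlap between 12 females and 12 males. The block held 42 tiles lower in males and 2 higher, and chromosome 17 held 12 clusters rather than a single block, so the explanation was met only in part. Copies on the Y and a difference in methylation of the autosomal genes cannot be told apart, since neither Y sequence nor coverage was used here. The sex of the animals as a biological cause stays open.

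For the tile counts by limma, chance cannot be excluded within a sex, and 30 of 100 female and 12 of 100 male splits reached the real 5.32% and 6.12% of tiles with an unadjusted p under 0.05 (highest others 8.88% and 8.51%). In females 13 of 100 splits gave at least the real 5 tiles (highest other 1275, which points to structure among the female libraries), and in males 15 of 100 gave at least 5 (highest other 155). The first principal component of the 24 libraries held 12.4% of the variance, with no score between -0.1255 and 0.1263. All 4 groups had libraries on both sides, but in males the only control on the positive side was replicate 3, against choline replicates 1, 2 and 6. On the second component, with 8.66% of the variance, female choline 1 and 3 and male choline 1 and 6 scored 0.363 to 0.444. The other choline libraries scored -0.226 to 0.0841, and the controls -0.260 to 0.0610. On the third, with 6.44%, male controls were positive except replicate 4, and male choline libraries negative except replicate 6. Both female groups lay on both sides of it. Whether these components follow the treatment was not tested. No test was adjusted for any component, and their causes are unknown. Over both sexes 1 of 100 splits, the real one, gave as many as the real 8 tiles (highest other 2), the fewest that 100 splits can give. Other splits thus rarely reached this count, which was 1 of several compared in this way without adjustment. This holds for that count only, since 6 of 100 splits reached the real 6.77% of tiles with an unadjusted p under 0.05 (highest other 8.04%), and the count fell to 0 on the offset tiles and without any of 9 libraries. For the difference between the sexes in the effect of choline, 100 of 100 splits gave at least the real 0 tiles (highest other 10). For promoters, 100 of 100 splits gave at least the real 0 in females, males, both sexes and the difference, where limma found 1258, 1345, 1517 and 925 at an unadjusted p under 0.05 (highest others 2, 1, 2 and 2). Every split gives at least 0, so these counts of 100 were fixed in advance and say nothing about chance, for promoters and for the difference between the sexes alike. The real numbers of promoters with an unadjusted p under 0.05 were reached by 42 of 100 splits in females (highest other 2386), 22 in males (highest other 2213) and 11 over both sexes (highest other 2130), so chance cannot be excluded for these.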

How the results depend on the processing

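Leaving out libraries over both sexes and in the difference between the sexes, and the alternatives for the tiles that differ between the sexes, were chosen after seeing the data. Of 2331 values under alternatives, 2017 were labelled the same and 217 lost the call. A further 63 were counts that moved, and 34 values reversed, 0 of them by leaving out a library. The label meant the same direction and side of the threshold, or a count close to the original without having to equal it. For tiles of the authors' regions it meant the same direction and a shift below the within-group SD. Most of the 2017 had no limma call to lose. For the called tiles, leaving out a library kept the call in 29 values and lost it in 31 in females, in 24 and 36 in males, and in 72 and 120 over both sexes. Tile counts were 3 in females, 2 in males and 4 over both sexes on the log2 scale, of which 0, 1 and 1 were among the tiles called in percent; 10 in each sex with all overlapping tiles; 8 in females and 0 over both sexes on the offset tiles; and 16 over both sexes at means of 10 to 90%. Leaving out a library gave 1 to 31 tiles in females, 0 to 31 in males, 0 to 31 over both sexes and 0 to 1 for the difference between the sexes (1 without female control 4). In females the count was 1 without control 1, 21 without control 2, 3 without control 3 or 5, 8 without control 6, 11 without choline 1 or 5, 31 without choline 2, 3 without choline 3 or 6 and 1 without choline 4. In males it was 0 without control 1, 2 or 5, 31 without control 3, 22 without control 4, 18 without control 6, 3 without choline 1, 9 without choline 4 and 11 without choline 6. Over both sexes it was 0 without female control 1, 2 or 6, male control 1, 2, 5 or 6 or male choline 3 or 6, 17 without female control 4 or male choline 2, 19 without female control 5, 31 without female choline 2, 4 without female choline 1, 3 without male control 3, 2 without female choline 3 or male choline 1, and 1 without female choline 6 or male choline 5. Over both sexes 1 promoter passed on the log2 scale, with the 3000-base window and with libraries shifted to a common mean, and in males 0 to 1 passed without a library (1 without control 3, control 6 or choline 5). The replicate numbers did not pair the libraries, as those of the same number correlated at -0.169 to 0.00656 in females and -0.0860 to 0.0324 in males, and under pairing (block) 0 tiles passed in either sex. The difference in mean methylation ranged from 0.0409 to 0.434 in females and from -0.383 to -0.0664 in males without a library. The authors' regions numbered 3412 in females and 3521 in males at a q-value under 0.01 and 25 points, 141513 and 139318 at 10 points, and 3 and 5 tiles by limma with at least 20 points; shared tiles were then 76 at the stricter thresholds. The 299 tiles between the sexes became 219 to 284. With the 3000-base window, female *TET1* became -0.803, *DNMT1* -0.0655, *PEG10* -1.91 and *TFRC* 0.0656, male *PPP1R9A* -0.677, the insulin and lipid list 0.00483 in females and 0.0871 in males, and the male one-carbon list -0.217. On offset tiles, female *GZMM* became 0.192 and male *PRKAG3* -0.354. Relative to the library mean, female autosomes became -0.0106, promoters -0.0847, -0.0692 and -0.0602 with distance, 5' UTR -0.120, exon -0.119, intron -0.0535, 3' UTR -0.0724, downstream -0.119, levels under 20% -0.0123, levels over 80% -0.0783, the one-carbon list -0.155 and the growth list -0.134. In males, promoters became 0.124, 0.101 and 0.0805, 5' UTR 0.0763, exon 0.123, intron 0.0440, 3' UTR 0.149, downstream 0.0149, levels of 20 to 80% 0.0935, the methylation machinery list 0.0869 and the insulin and lipid list 0.0135. The cause of these changes was not tested. The unknown depth limits the precision of single tiles.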

Other observations

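The means over both sexes of the gene lists were tests chosen after the values within each sex were seen.

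Genes of the lists fixed in advance that held an authors' called tile in both sexes were *ETNK1*, of ethanolamine phosphorylation, and *MTRR*, of methionine synthase reduction, in the choline and one-carbon list, the demethylase gene *TET2*, *PLA2G4A*, the transcription factor genes *EOMES*, *TFAP2A* and *GATA3*, *SYCP1*, *IL5RA* and the lipopolysaccharide receptor gene *TLR4*. In females, a called tile was found for 1 of 47 growth genes where the number of tiles alone would give 12, for 2 of 37 imprinted genes against 9.71, and for 2 of 54 developmental transcription factors against 8.83. In males the counts were 6 against 12.2, 5 against 9.27 and 3 against 9.09. Most other lists were also below the number expected, such as choline and one-carbon metabolism at 5 against 9.44 in females and 6 against 9.47 in males. Only neutrophil and eosinophil markers, at 3 against 2.19 in females and 3 against 2.27 in males, and red cell and platelet markers in males, at 2 against 1.76, were above it. No test of these counts was run.

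Over both sexes, monocyte marker promoters were higher by 1.42 points with choline (exact permutation p = 0.0217, adjusted p = 0.130), red cell and platelet promoters by 0.808 (exact permutation p = 0.0155, adjusted p = 0.130) and neutrophil and eosinophil promoters by 1.34 (exact permutation p = 0.112, adjusted p = 0.337). B cell promoters differed by -1.79 (exact permutation p = 0.0996, adjusted p = 0.337) and T and NK cell promoters by -0.489 (exact permutation p = 0.559, adjusted p = 0.671). None passed after adjustment over 12 lists. The other 7 lists had adjusted p values of 0.491 or more.

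The mitochondrial means of all 12 females lay above those of all 12 males. The difference with choline was -0.0639 points in females, and none was found in males (exact permutation p = 0.957). Whether the effect differed between the sexes was not tested. Over both sexes, also chosen afterwards, the difference was -0.0322 points (exact permutation p = 0.0130, not adjusted). No explanation of these low levels was tested.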
